A study of Mus musculus with 15 samples.

How the data were processed

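The series holds 15 bead arrays of RNA from mouse spleen, taken as an unsorted suspension of single cells. Per the labels, all mice belong to a model in which Cbx7 is overexpressed, and each mouse with a type label had a T-cell, an erythroid or an undifferentiated leukemia. Per the labels' protocols, the RNA was isolated on RNeasy columns, amplified as whole transcriptome with a NuGEN kit for small inputs, and hybridised as biotin-labelled single-stranded cDNA. The leukemia type was given for 14 arrays from 12 mice: 8 arrays of 7 mice with T-cell leukemia, 5 arrays of 4 mice with erythroid leukemia and 1 array of 1 mouse with undifferentiated leukemia. Mouse 5-1 (T-cell) and mouse 5-5 (erythroid) were each run on 2 arrays. The remaining array had neither a mouse nor a type in its labels and entered no comparison.

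The authors deposited a mean bead intensity and a detection p-value for each of 25697 probes on each array, without normalization between arrays; the software that made these summaries is not given in the sources used here. The detection p-values deposited with the intensities compare each probe with the negative controls of its array. The authors also deposited a table of processed values for the same arrays, which lie on a log2 scale and have nearly the same distribution in every column. Per the submitters' processing notes, limma and R 3.0.2 were used to make it, and the method of normalization is not stated there. Its columns correlated with the values computed here at 0.99998 or above over all probes, the medians of its columns ran from 4.81 to 4.83, and the median absolute difference from the values used here was 0.000814. Its scale and direction were therefore settled from the intensities, and it served as an alternative.

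From the intensities and detection p-values, normalised values were computed with neqc of limma 3.58.1 in R 4.3.3: a normexp background correction that takes the negative controls from the detection p-values, an offset of 16, quantile normalization over all 15 arrays and log2. Probes with a detection p under 0.05 on at least 3 of the 14 labelled arrays were kept, which left 14432 probes. Arrays of the same mouse were averaged. Of several probes for 1 gene, the probe with the highest mean was used, so 10474 genes were tested; 2703 of them had more than 1 probe past the filter. For Traf4, probes passed the threshold in opposite directions between the erythroid and T-cell leukemias, and for 373 genes with several probes only some passed. The files' gene symbols were brought up to date through an NCBI RefSeq gene table of the mouse assembly GRCm38.p6, used only for names. Of the probes, 20733 already had a current symbol, 3677 were renamed through a synonym, 226 kept the symbol in the file because the current symbol stood for another probe, and 1061 had no match and kept the symbol in the file. No coordinates are given, because no genome build is named for the probes.

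Linear models were fitted with lmFit and eBayes of limma to the 12 labelled mice, with the leukemia type as the only term and 1 shared estimate of the spread. P-values were two-sided and adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The contrasts were erythroid minus T-cell, undifferentiated minus T-cell and undifferentiated minus erythroid. The single undifferentiated mouse was assumed to vary like the mice of the other groups. The first number of the mouse titles (2, 4 or 5) is shared by several mice, and the labels do not say what it marks. A second model with a mean for each combination of type and number tested whether the T-cell leukemias of the 3 numbers differed, whether the erythroid leukemia of number 5 differed from those of number 2, and whether the erythroid minus T-cell change differed between numbers 5 and 2. Mice that share a number may not be independent of each other, and p-values then understate the error. Erythroid mice 2-3, 2-3-2 and 2-3-3 also share a second number. The mice with 1 number in the title (2 and 5) had T-cell leukemia, and those with 3 (2-3-2 and 2-3-3) had erythroid leukemia. The labels do not say what the count of numbers marks, and the erythroid minus T-cell change was not adjusted for it. A check whether mice of the same number deviate together is given with the alternatives. The series has no mouse without Cbx7 overexpression, so no background level from such mice could be set beside any value.

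The comparisons, the gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined. The genes named between erythroid and T-cell leukemias were the 10 with the largest change in each direction among those past the threshold whose mice did not overlap between the types. Up to 5 members of each list with the smallest adjusted p, list members that passed against the majority of their list, and Cbx7 were added. For the undifferentiated leukemia, the rule took up to 8 genes per direction past the threshold and up to 3 members per list; for the leading numbers, it took up to 10 genes past the threshold in each test. Only part of the genes the rule allows are named, and some results on single genes are not reported here. A probe with no detected signal on any array of a group has only an upper limit there. The difference is then given as "at least" a fold. For it, the mean of the brighter group was set against the mean, per array, of the higher of the probe's own value and the lowest value among detected probes.

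The 29 gene lists covered T-cell, erythroid, other blood and stromal cells, proliferation, polycomb complexes, p53, interferon and metabolism. A total of 28 lists had at least 3 measured members and were tested; the list of embryonic globins had 0 members past the detection filter and was not. Lists were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a contrast. Camera compares a list with the other genes, whereas fry tests whether the members move, on balance, in 1 direction and makes no comparison with other genes. Counts of members are given over all genes tested and adjusted over the list alone.

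The model was tested on simulated data in which 50 genes were changed by each size. For erythroid against T-cell, it recovered 20% of genes changed by 1 on the log2 scale, 88% of those changed by 2 and 98% of those changed by 3. For undifferentiated against T-cell, it recovered 38% at 2 and 82% at 3. For the T-cell leading numbers, it recovered 30% at 2 and 94% at 3. For erythroid number 5 against 2, it recovered 8% at 2 and 72% at 3. For the difference of changes between numbers, it recovered 4% at 2 and 18% at 3. The number of arrays limits the precision of all values.

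The alternatives were the authors' value table, quantile normalization without background correction, normexp with an offset of 50, cyclic loess, median scaling, quantile normalization over the 14 labelled arrays, no filter, a strict filter (detection p under 0.01 on at least 7 arrays), all filtered probes, all 14 arrays with the mouse as a random block, the first array only of mice 5-1 and 5-5, eBayes with trend and robust, array quality weights, the leading number as a fixed or random block, mice that share a type and number averaged, an absolute log2 fold change of at least 1, and leaving out each mouse in turn. Added after the data were seen were fits without the 2 arrays on which the fewest probes were detected and fits that treat the array number (1 to 8 or 9 to 16 in the labels) as a batch. Mice 5-1 and 5-5 had an array in each of these number ranges. Slide and scan date are not given in the sources used here. Figures were drawn with matplotlib 3.10.9.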

Results

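Gene expression was measured on bead arrays in unsorted spleen cells of mice from a model of leukemia driven by overexpression of Cbx7, a chromobox protein of polycomb repressive complex 1. The title of the series names the dynamics and the heterogeneity of these leukemias, followed with barcodes, as its subject. Of the 12 mice with a type label, 7 had T-cell leukemia (mice 2, 5, 4-1, 2-2, 5-1, 4-2 and 5-3), 4 had erythroid leukemia (mice 2-3, 5-5, 2-3-2 and 2-3-3) and 1 had undifferentiated leukemia (mouse 4-3). Mice 5-1 and 5-5 were run on 2 arrays each. The T-cell arrays detected 11278 to 12944 of 25697 probes and the erythroid arrays 7382 to 12605. The 2 lowest numbers, 7382 on the second array of mouse 5-5 and 7554 on the array of mouse 2-3-2, both came from erythroid leukemias; the undifferentiated array detected 11699. Over the genes tested, the 2 arrays of mouse 5-1 correlated at r = 0.972, and those of mouse 5-5 at r = 0.834. The median r was 0.887 for arrays of different mice with the same leukemia type and 0.792 for arrays of different types, so the arrays of mouse 5-5 matched each other less well than the median pair of different mice of the same type.

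**Figure D1:**
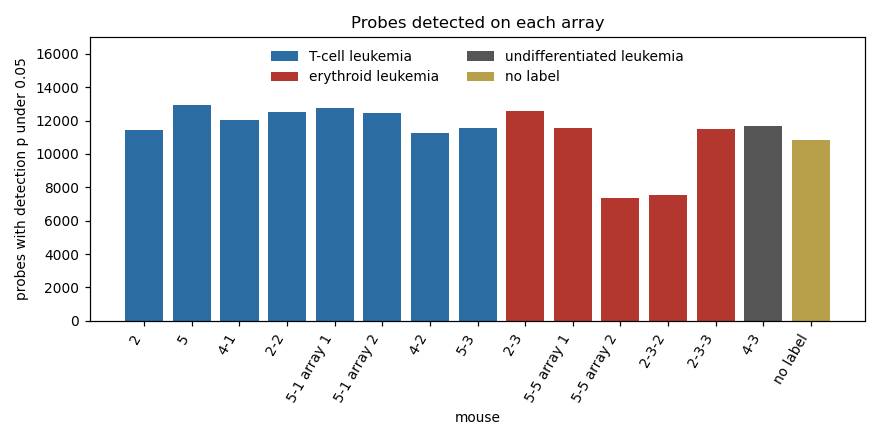
Number of probes with a detection p under 0.05 on each of the 15 arrays, with a bar per array coloured by leukemia type and mice in order of type. The second array of mouse 5-5 and the array of mouse 2-3-2 detected 7382 and 7554 probes, and the other labelled arrays detected 11278 or more.

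The overexpressed gene itself was close to background on these arrays. The Cbx7 probe (ILMN_2947234) was detected on 2 of 14 labelled arrays, in T-cell leukemia mice 5 and 4-2, and its log2 signal was 4.81 ± 0.19 (SD, n = 7) in T-cell and 4.54 ± 0.12 (SD, n = 4) in erythroid leukemias. It was detected on no erythroid array, so the erythroid value is an upper limit near background, and the gene was not among those tested. All labelled samples carry the overexpressed gene and a transcript from a vector may lack the sequence that the probe reads, so the probe does not check the model.

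The first comparison asked how the erythroid leukemias differed from the T-cell leukemias. Genes past the threshold whose mice did not overlap between the types were ranked by their change. Among them, the largest increase in erythroid leukemias was that of a gene of the red cell surface and the largest decrease that of a gene of the T-cell receptor. Kel, which encodes the Kell blood group protein (probe ILMN_2668996), had a log2 signal of 9.77 ± 0.34 (SD, n = 4) in erythroid and 6.50 ± 1.63 (SD, n = 7) in T-cell leukemias, a 9.65-fold difference (log2 3.27 ± 0.72 SE, limma adjusted p = 0.0162). Cd3d, a chain of the T-cell receptor complex (probe ILMN_2697415), had a log2 signal of 5.75 ± 1.31 (SD, n = 4) in erythroid and 10.27 ± 0.89 (SD, n = 7) in T-cell leukemias, a 22.9-fold difference (log2 -4.52 ± 0.57 SE, limma adjusted p = 0.00144). Across all genes, 1075 of 10474 passed the threshold, 404 higher and 671 lower in erythroid leukemias, and 948 of them differed by at least 1 on the log2 scale. All erythroid mice lay above all T-cell mice for 264 genes and below them for 490 genes, or 2.52% and 4.68% of the genes, where chance gives 0.303% in each direction.

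After Kel, the largest increases among these genes with no overlap included those of Pklr, the pyruvate kinase of liver and red cells (log2 3.26 ± 0.70 SE), and Nupr1, a stress-induced nuclear protein (3.08 ± 0.63). Also among them were Ppox, an enzyme of heme synthesis (2.76 ± 0.43), and the probe listed as Clca1 (2.75 ± 0.64), a symbol that has been used for more than 1 gene. Cpeb4, an RNA-binding protein, Map4k5, a kinase, Ppp1r15a, a regulatory subunit of a phosphatase in the stress response, and Ermap, an erythroblast membrane protein, were higher by 2.74, 2.72, 2.71 and 2.68. After Cd3d, the largest decreases among the genes with no overlap were those of Cd3g (-4.38 ± 0.46), the unnamed locus LOC100048845 (-4.33 ± 0.47), Trim36 (-4.26 ± 0.61) and the surface glycoprotein gene Thy1 (-4.14 ± 0.53). Tcf7, which encodes a transcription factor of T-cell development, had a log2 signal of 4.76 ± 0.13 (SD, n = 4) in erythroid and 8.79 ± 0.83 (SD, n = 7) in T-cell leukemias and had the smallest adjusted p of the genes named here (0.000727). Rasgrp1, an activator of Ras below the T-cell receptor, and Tnfsf11, which encodes RANKL, both fell by 3.84, Dzip1 fell by 3.76 and Hectd2 fell by 3.72. The adjusted p of the genes named in this paragraph, Cd3d and Kel ran from 0.000727 for Tcf7 to 0.0442 for Ermap. The increases depended on the scaling more than the decreases did. Under median scaling, which moved the median change of all genes to -0.22, each of the 65 named genes past the threshold kept its sign, but 6 of 35 higher and 22 of 30 lower genes passed. Kel stood at 2.88 (adjusted p = 0.0656) in that setting and Pklr at 2.84 (0.061), while Ppox (2.27, 0.0243), Cpeb4 (2.41, 0.0306) and the 10 genes with the largest decreases in this ranking passed.

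**Figure D2:**
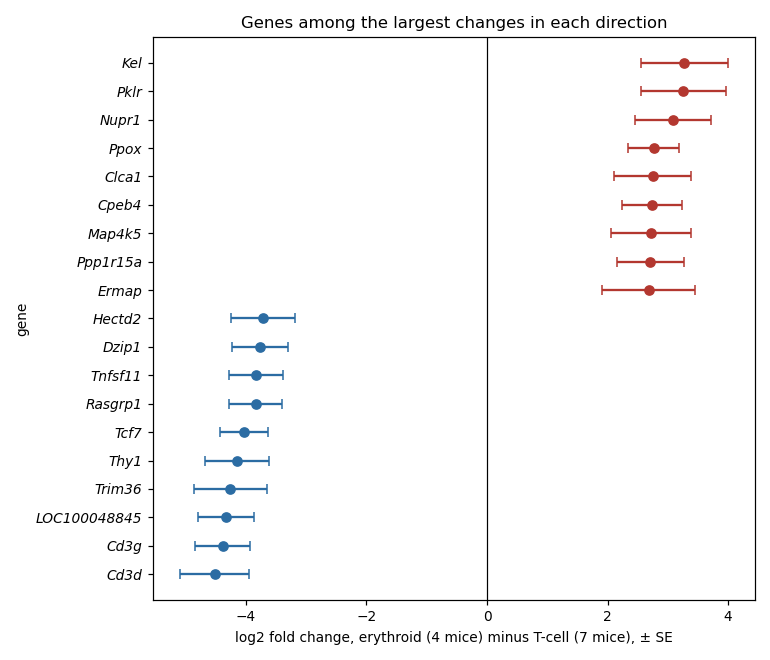
Log2 fold change between erythroid (n = 4) and T-cell (n = 7) leukemias for genes among the 10 with the largest change in each direction of those past the threshold with no overlap between the types, with points for the fitted change and bars for 1 SE. The changes run from -4.52 for Cd3d to 3.27 for Kel.

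Most measured genes of the T-cell receptor were lower in erythroid leukemias. In the list of T-cell receptor and signalling genes, 18 of 27 measured members were lower, none was higher and 9 did not pass; adjusted over the list alone, 21 were lower. Besides Cd3d, Cd3g, Thy1 and Rasgrp1, the adhesion molecule gene Cd2 fell by 3.45 on the log2 scale. In the list of thymocyte and early T-cell development genes, 8 of 15 were lower, with 9 lower and 1 higher adjusted over the list alone. Next to Tcf7, the chromatin organiser Satb1 (-3.22) and the transcription factors Bcl11b (-3.03) and Ets1 (-3.01) had the smallest adjusted p. The median member changed by -2.37 in the first list and by -1.42 in the second (camera adjusted p = 3.05e-13 and 2.12e-05 at the preset correlation). Neither call held with an estimated correlation (adjusted p = 0.284 for both), and both held with fry (adjusted p = 0.00414 and 0.0198). In the list of the Notch pathway and its targets, 2 of 13 members passed, over all genes and adjusted over the list alone, and went opposite ways. Notch1, a receptor with a known role in T-cell leukemia, was not detected on any erythroid array and was at least 2.23-fold lower (adjusted p = 0.0368), whereas Nrarp, a feedback inhibitor of Notch, rose by 0.93 (adjusted p = 0.0347). Each of the 2 passed in 14 of 27 alternative settings and not under median scaling (adjusted p = 0.0813 and 0.456), and both stood apart in T-cell mouse 5-1. The list as a whole did not pass (median -0.35, camera adjusted p = 0.402).

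Many erythroid genes were higher in erythroid leukemias. In the list of erythrocyte membrane and terminal erythroid genes, 15 of 33 measured members were higher, none was lower and 18 did not pass; adjusted over the list alone, 25 were higher. Besides Kel and Ermap, the membrane skeleton genes Dmtn (log2 2.17 ± 0.39 SE) and Add2 (1.64 ± 0.28), the nuclear factor Hemgn (2.35 ± 0.46) and Bpgm, the enzyme that makes bisphosphoglycerate in red cells (1.77 ± 0.37), passed. In the heme synthesis list, 10 of 14 were higher, with 12 higher and 1 lower adjusted over the list alone. Next to Ppox they included the transporter Abcb10 (2.36 ± 0.45) and the enzymes Uros (2.25 ± 0.37) and Alad (1.84 ± 0.42). Of 19 erythroid transcription factors and genes of erythropoietin signalling, 6 were higher and 1 was lower, or 12 and 1 adjusted over the list alone. The higher ones included Sox6 (2.57), Gfi1b (2.41), Lyl1 (1.89) and the erythropoietin receptor Epor (1.26), and the lower one was Stat5b (-0.86, adjusted p = 0.046), which signals below this and other cytokine receptors. The median member of these lists changed by 2.26, 1.91 and 1.26 (camera adjusted p = 3.01e-13, 3.45e-07 and 0.000161 at the preset correlation). None of the 3 calls held with an estimated correlation (adjusted p = 0.284 for each), and all held with fry (adjusted p = 0.0248, 0.0198 and 0.0272). Under median scaling, Ppox, Abcb10, Add2 and Bpgm passed among the genes named here. Sox6, Gfi1b, Lyl1, Epor (0.73) and Stat5b did not (adjusted p = 0.110, 0.131, 0.160, 0.200 and 0.0700), nor did Kel, Ermap, Dmtn, Hemgn, Uros and Alad (0.0656 to 0.148).

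Adult globin transcripts were abundant in both types and did not pass. Hbb-b1 had a log2 signal of 13.08 ± 0.69 (SD, n = 4) in erythroid and 11.79 ± 2.00 (SD, n = 7) in T-cell leukemias (adjusted p = 0.367). Hba-a1 stood at 12.21 ± 0.40 and 10.85 ± 2.07, and Hbb-b2 at 11.93 ± 0.51 and 10.60 ± 1.93. Globin genes have near-identical copies that their probes may not tell apart. The mean of the 3 measured globins ran from 7.05 in mouse 4-2 to 12.76 in mouse 2-2 among the T-cell leukemias. The list did not pass (median 1.33, camera adjusted p = 0.255), and 0 members passed adjusted over the list alone. Within arrays 9 to 16 alone, the list passed at the preset correlation (median 2.38, camera adjusted p = 0.0495); over all arrays the estimated correlation was 0.985, and the adjusted p with it was 0.670.

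Some genes of cell division were higher in erythroid leukemias. In the mitosis list, 6 of 25 members were higher, none was lower, and 12 were higher adjusted over the list alone; they included Hmmr (log2 1.53 ± 0.32 SE), Tpx2 (1.26), Ccna2 (1.14) and Prc1 (1.01), which act in the spindle and in entry to mitosis. In the DNA replication list, 4 of 28 were higher, over all genes and adjusted over the list alone, among them Mcm10 (1.70 ± 0.35), Cdc6 (1.32) and Rfc5 (0.89 ± 0.19). The medians were 0.68 and 0.63 (camera adjusted p = 1.44e-06 and 4.15e-06 at the preset correlation). Neither held with an estimated correlation (adjusted p = 0.431 and 0.534); with fry, mitosis passed (adjusted p = 0.0486) and DNA replication did not (0.0971). Under median scaling, both lists passed with camera (medians 0.45 and 0.27, adjusted p = 3.44e-05 and 0.00032), but none of the 7 genes named here did, with changes from 0.37 for Rfc5 (adjusted p = 0.608) to 1.17 for Mcm10 (0.139).

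Several polycomb genes were lower in erythroid leukemias, while the signal of Cbx7 was too close to background to compare. Cbx6, which encodes a chromobox protein of the same family as Cbx7, fell by 2.25 on the log2 scale, and Bmi1, a core member of polycomb repressive complex 1, fell by 1.61 (adjusted p = 0.0068 and 0.0089). Under median scaling both passed as well (adjusted p = 0.00635 and 0.0218). Among the erythroid mice, Cbx6 stood apart in mouse 5-5, at 9.89 against 7.85 to 8.19 in the others. Of 16 measured members of the complex, 3 were lower and none was higher, and 6 were lower adjusted over the list alone. Their mean was 5.90 in erythroid mouse 2-3-2, whose array was among the weakest, and 6.26 to 6.33 in the other erythroid mice. The list had a median of -0.42 and did not pass with camera (adjusted p = 0.0506, and 0.284 with an estimated correlation) but passed with fry (adjusted p = 0.0138) and with camera in several other settings, such as median scaling (median -0.66, adjusted p = 0.0384) and no filter (-0.37, 0.00326). Of 9 members of polycomb repressive complex 2, Jarid2 was lower (-1.78, adjusted p = 0.0139), the single one also when adjusted over the list alone (list median -0.07, camera adjusted p = 0.541). None of the 6 CDK inhibitors passed, over all genes or adjusted over the list alone. Their median was -0.12, their mean -0.0022 and camera's direction up (adjusted p = 0.861). Of the stem and progenitor genes, 2 of 20 were lower, Gfi1 (-3.0, adjusted p = 0.00244) and Hoxa9 (-0.99, adjusted p = 0.0376); adjusted over the list alone, 2 were lower and 1 was higher (list median 0.31, camera adjusted p = 0.47). Under median scaling, Gfi1 passed (limma adjusted p = 0.00356) and Hoxa9 did not (0.0656). Hoxa9 passed in 11 of 27 alternative settings. Gfi1 is also a transcription factor of T-cell development.

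Spleen holds other blood cells, and markers of some of them moved with the leukemia type. In the list of megakaryocyte and platelet genes, 2 of 14 were higher in erythroid leukemias, over all genes and adjusted over the list alone: Itga2b, an integrin of platelets (log2 2.05 ± 0.53 SE), and the thrombin receptor gene F2rl2 (1.56 ± 0.39). Itga2b passed in 13 and F2rl2 in 16 of 26 alternative settings, and neither did under median scaling (adjusted p = 0.0884 and 0.179). The platelet chemokine Pf4 stood at 7.35 ± 2.02 (SD, n = 4) in erythroid and 5.05 ± 1.25 (SD, n = 7) in T-cell leukemias (adjusted p = 0.0927). This list passed with camera (median 0.75, adjusted p = 0.00473; 0.284 with an estimated correlation) and with fry (adjusted p = 0.0248), but not with the strict filter (median 1.02, camera adjusted p = 0.0747). In the list of MHC class II and dendritic genes, 2 of 11 were lower, over all genes and adjusted over the list alone: H2-DMb2 (-2.59) and H2-DMa (-2.29), which load peptides onto class II molecules. It passed with camera (median -0.92, adjusted p = 0.042; 0.640 with an estimated correlation) and not with fry (adjusted p = 0.150), under median scaling (-0.78, 0.0752), with cyclic loess (-0.47, 0.0907), with no filter (-0.40, 0.118), with the strict filter (-1.58, 0.0577) or without the 2 weakest arrays (-0.79, 0.0590). Its call was also lost when any of 5 of the mice was left out, with adjusted p up to 0.179 without erythroid mouse 2-3-3. Of 14 B-cell genes, Cd37 was lower (-2.03) and Btk higher (1.57), over all genes and adjusted over the list alone (median -0.52, camera adjusted p = 0.104; with all filtered probes -0.64 and 0.00228, with an estimated correlation 0.670). Btk is also used by myeloid cells. Of 9 genes of NK and cytotoxic cells, Il2rb was lower (-1.66, adjusted p = 0.0314; list median -0.07, camera adjusted p = 0.47), over all genes and adjusted over the list alone. Of 10 genes of mast cells and basophils, Il4, which T cells also make, was not detected on any erythroid array and was at least 2.68-fold lower (adjusted p = 0.0456), over all genes and adjusted over the list alone. That list had a median of 0.07, a mean of -0.12 and camera's direction down (adjusted p = 0.843). Of the genes named in this paragraph as past the threshold, H2-DMa alone passed under median scaling (adjusted p = 0.0444).

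No member passed, over all genes or adjusted over the list alone, in the lists of 18 granulocyte, 21 monocyte and macrophage, 8 plasma cell and 9 stromal and endothelial genes. Their medians were 0.37, 0.33, -0.35 and -0.38 (camera adjusted p = 0.273, 0.255, 0.536 and 0.47). In other settings 2 of these lists passed at the preset correlation. The monocyte list did so within arrays 1 to 8 (median 0.68, camera adjusted p = 0.0033), within arrays 9 to 16 (0.73, 0.0495) and without the 2 weakest arrays (0.73, 0.0326), and the granulocyte list within arrays 9 to 16 (0.50, 0.0263) and under median scaling (0.25, 0.0384). Over all arrays, the estimated correlations of these 2 lists were 0.388 and 0.616, and neither passed with them (adjusted p = 0.756 for both) or with fry (0.657 and 0.670). The granulocyte mean varied within both types. It ran from 4.95 in mouse 4-1 to 8.85 in mouse 2-2 among T-cell leukemias and from 5.32 in mouse 2-3-2 to 7.90 in mouse 2-3 among erythroid leukemias.

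**Figure D3:**
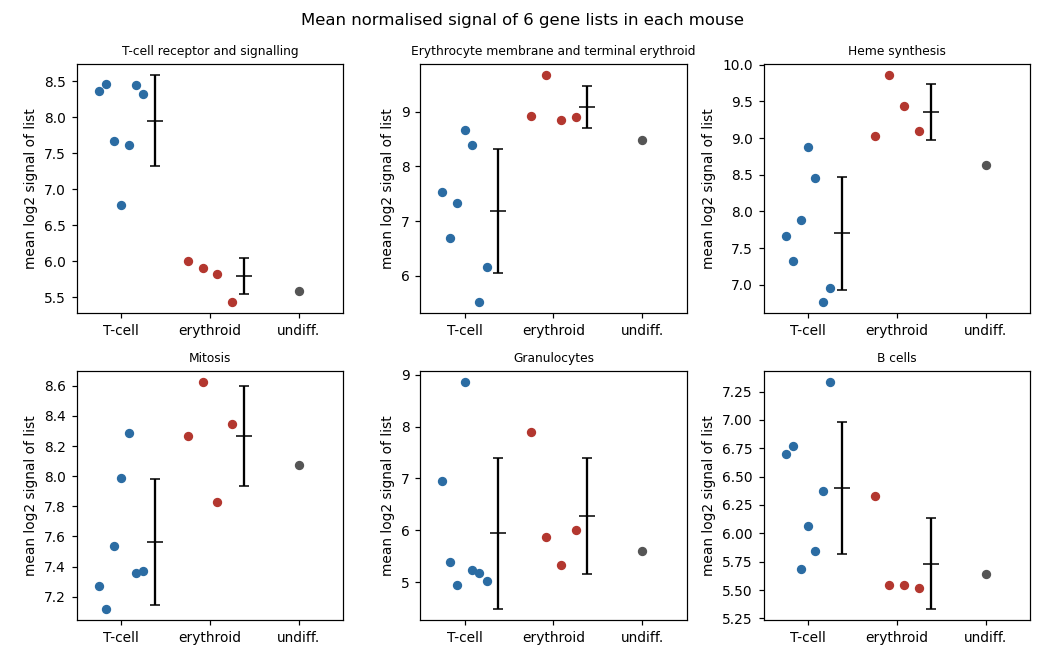
Mean log2 normalised signal of 6 gene lists in each mouse, with a point per mouse and a bar for the mean ± SD of the types with more than 1 mouse. The T-cell receptor list lies between 6.79 and 8.47 in T-cell and between 5.44 and 6.01 in erythroid leukemias, while the granulocyte list spreads widely within both types.

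In the interferon response list, 3 of 22 members were higher in erythroid leukemias, Ifit1 (log2 2.62 ± 0.50 SE), Irf9 (1.51 ± 0.33) and the RNA sensor gene Ifih1 (1.37 ± 0.38), and 4 were higher adjusted over the list alone. Under median scaling, Ifit1 passed (adjusted p = 0.0411), and Irf9 and Ifih1 did not (0.0803 and 0.386). The list passed with camera (median 0.89, adjusted p = 0.000473; 0.569 with an estimated correlation) and not with fry (adjusted p = 0.150). Its mean was 8.92 in mouse 5-5 and 6.63 to 7.15 in the other erythroid leukemias, and without mouse 5-5 the list did not pass (median 0.32, camera adjusted p = 0.0871). Of 10 MHC class I genes, the immunoproteasome gene Psmb8 was lower (-2.10, adjusted p = 0.0241; list median -0.19, camera adjusted p = 0.255), over all genes and adjusted over the list alone. Of 18 p53 targets, 2 were higher, among them Sesn1 (0.77 ± 0.21), and 4 were higher and 1 lower adjusted over the list alone (median 0.17, camera adjusted p = 0.255). Of 13 immediate early and heat shock genes, the growth-response transcription factor Egr1 was lower (-2.43, adjusted p = 0.0103), over all genes and adjusted over the list alone, while the median of the list was 0.44 (camera adjusted p = 0.47). Of 14 glycolysis genes, the pyruvate kinase gene Pkm was lower (-1.76, adjusted p = 0.00853), and 2 were lower adjusted over the list alone (median -0.48, camera adjusted p = 0.104; with no filter -0.39 and 0.00365, with an estimated correlation 0.640). Of 15 genes of cholesterol synthesis, Lss was lower (-1.72, adjusted p = 0.0496), and 0 passed adjusted over the list alone. That list had a median of 0.06 and a mean of -0.0023, with camera's direction up (adjusted p = 0.823). Under median scaling, Psmb8, Egr1 and Pkm passed (adjusted p = 0.0476, 0.0188 and 0.0352), and Sesn1 and Lss did not (0.643 and 0.141).

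The number of genes past the threshold was far lower with the leading number as a fixed block, as given with the alternatives. The number also depended on single mice and on the scaling. It fell to 538, 493, 577 and 656 without T-cell mice 2, 5, 4-2 and 5-3 and to 460, 558 and 635 without erythroid mice 5-5, 2-3-2 and 2-3-3, median scaling gave 44 higher and 387 lower genes, no filter gave 577 genes and array quality weights gave 1993. Without the 2 arrays with the fewest detected probes, a setting chosen after seeing the data, 591 genes passed, 470 of them among the 1075. The array numbers in the labels were also used as a batch after the data were seen. With the number range (1 to 8 or 9 to 16) as a term, 1118 genes passed. Within arrays 1 to 8, with 2 erythroid and 5 T-cell mice, 0 passed with limma (1803 at an unadjusted p under 0.05), and within arrays 9 to 16, with 3 mice of each type, 179 passed. The T-cell receptor list had a median change of -2.37 with that term, -1.91 within arrays 1 to 8 and -2.44 within arrays 9 to 16. For the erythrocyte membrane list these values were 2.34, 1.73 and 2.81, for heme synthesis 1.99, 1.47 and 2.29, for erythroid transcription factors 1.32, 1.12 and 1.70, and for thymocyte genes -1.40, -1.10 and -2.0. For mitosis they were 0.81, 1.03 and 0.51, for DNA replication 0.66, 0.77 and 0.41, and for interferon response 1.14, 1.55 and 1.25. All of these lists passed in each setting with camera at the preset correlation. Over all arrays, none of them passed with an estimated correlation (camera adjusted p = 0.284 to 0.569). Mice 5-1 and 5-5 had an array in each range, so the 2 ranges are not independent of each other. The interferon list, which did not pass over all arrays without mouse 5-5, included that mouse in both ranges. Within arrays 1 to 8, the calls of the megakaryocyte list (median 0.44, camera adjusted p = 0.170) and of the MHC class II list (-0.15, 0.616) were lost; with the term, their medians were 0.73 and -0.88, and within arrays 9 to 16 they were 0.88 and -1.64. With the term in the fit, the lists of monocytes and macrophages (0.52, camera adjusted p = 0.0478), B cells (-0.58, 0.0478) and polycomb repressive complex 1 (-0.43, 0.0478) passed as well. Within arrays 9 to 16, the B-cell (-0.73, camera adjusted p = 0.0281) and glycolysis lists (-0.60, 0.0495) passed. These calls of the monocyte, B-cell, polycomb and glycolysis lists were also made at the preset correlation. Over all arrays, none of these lists passed with an estimated correlation (camera adjusted p = 0.284 to 0.756).

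The single undifferentiated leukemia, mouse 4-3, was compared with the T-cell leukemias and had lower Bbx and Lbh. Bbx, which encodes a protein with an HMG box (probe ILMN_2669461), had a log2 signal of 5.05 in mouse 4-3 and 8.00 ± 0.36 (SD, n = 7) in T-cell leukemias, a 7.77-fold difference (log2 -2.96 ± 0.39 SE, limma adjusted p = 0.0307). Lbh, a transcriptional regulator of development (probe ILMN_2816180), stood at 6.64 in mouse 4-3 and at 10.63 ± 0.50 (SD, n = 7) in T-cell leukemias, a 16.0-fold difference (log2 -4.0 ± 0.55 SE, limma adjusted p = 0.0307). These were the 2 genes past the threshold, and 754 had an unadjusted p under 0.05, where chance gives 523.7. Cd3d, Cd3g and Tcf7 differed by -4.88, -4.07 and -3.99 without passing (adjusted p = 0.0841, 0.0841 and 0.0694), and Tcf7 was not detected in mouse 4-3, at least 14.0-fold below the T-cell leukemias. No list member passed over all genes. Adjusted over the list alone, 13 of 27 T-cell receptor genes, 6 of 15 thymocyte genes, 4 of 16 genes of polycomb repressive complex 1 and 3 of 14 glycolysis genes were lower, along with 2 of 13 immediate early genes, 1 of 18 p53 targets, and 1 lower and 1 higher of 20 stem and progenitor genes; in the other lists it was 0.

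With camera at the preset correlation, 15 lists passed between mouse 4-3 and the T-cell leukemias, 6 up and 9 down. Down were T-cell receptor (median -2.53, adjusted p = 2.69e-21), thymocyte (-1.03, 2.09e-07), MHC class II (-1.68, 4.79e-05), MHC class I (-0.86, 0.00193) and glycolysis genes (-0.51, 0.000957). Those up were the erythrocyte membrane (1.31, 1.04e-06), erythroid transcription factor (1.49, 4.96e-05), cholesterol synthesis (0.86, 7.24e-05), mitosis (0.48, 0.000799), DNA replication (0.44, 0.0025) and heme synthesis lists (1.14, 0.0026). The others down were B-cell (-0.60, 0.0165), plasma cell (-0.61, 0.0228), both lost with the strict filter (-0.31, 0.613 and -0.56, 0.173), NK and cytotoxic (-0.57, 0.00389) and polycomb repressive complex 1 genes (-0.11, 0.0121), a list whose median was 0.07 under median scaling, where camera still called it lower. The immediate early list, not past, had a median of 0.11 and a mean of -0.18. None passed with an estimated correlation (smallest adjusted p = 0.200, for T-cell receptor genes) or with fry (smallest adjusted p = 0.0901). The plasma cell list did not pass without T-cell mouse 5-1 (median -0.48, camera adjusted p = 0.0600). With 1 mouse there is no replicate check, and the genes past the threshold numbered 0 when any of T-cell mice 2, 5, 4-2 or 5-3 was left out. They numbered 63 without T-cell mouse 2-2, 28 without 4-1 and 13 without 5-1, and 4 and 6 without erythroid mice 5-5 and 2-3-2.

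Between mouse 4-3 and the erythroid leukemias, Bbx was again lower, at 5.05 against 8.16 ± 0.17 (SD, n = 4), an 8.66-fold difference (log2 -3.11 ± 0.41 SE, limma adjusted p = 0.0457). It was the single gene past the threshold, and 489 genes had an unadjusted p under 0.05, fewer than the 523.7 that chance gives. Camera called 5 lists at the preset correlation. The interferon response (median -1.07, adjusted p = 1.62e-06), megakaryocyte (-0.77, 0.000507), erythrocyte membrane (-0.73, 0.00517) and heme synthesis lists (-0.53, 0.0105) were lower in mouse 4-3, and cholesterol synthesis was higher (0.98, 0.000507). None passed with an estimated correlation (adjusted p = 0.784, 0.401, 0.784, 0.784 and 0.503 in that order) or with fry, and with no filter the erythrocyte membrane and heme synthesis lists did not pass (adjusted p = 0.0743 for both). These 2 lists did not pass without erythroid mouse 5-5 either (medians -0.55 and -0.35, camera adjusted p = 0.0830 for both), and the interferon median was -0.69 (adjusted p = 0.00167) without that mouse. No member of these 5 lists passed over all genes or adjusted over the list alone. Bbx passed in 9 of 25 alternative settings (adjusted p 0.00561 to 0.817) and no longer passed when any of T-cell mice 2, 5, 5-1, 4-2 or 5-3 or of erythroid mice 2-3, 5-5 or 2-3-3 was left out, with adjusted p from 0.0549 without mouse 5-3 to 0.170 without mouse 2-3-3. The genes past the threshold numbered 9 without T-cell mouse 4-1 and 2 without erythroid mouse 2-3-2.

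The next comparison asked whether T-cell leukemias of mice with the same leading number resembled each other, as a measure of heterogeneity. A single gene differed among the numbers 2 (2 mice), 4 (2 mice) and 5 (3 mice). On simulated data, this test recovered 0% of genes changed by 1 on the log2 scale and 30% of those changed by 2. The low count therefore does not show that the numbers are alike. Over the genes tested, T-cell mice of the same number correlated at r = 0.838 to 0.922 and those of different numbers at r = 0.816 to 0.965. The first range lies within the second, so by this measure mice of the same number did not stand out as more alike. Akr1c18, an aldo-keto reductase that degrades progesterone (probe ILMN_1260323), was detected in mice 4-1 and 4-2, with log2 signals of 9.27 and 10.61, and in no other T-cell leukemia. It was at least 31.9-fold higher in the mice of number 4 than in those of number 2 and at least 33.0-fold higher than in those of number 5 (limma F test, adjusted p = 0.00176). In the undifferentiated mouse 4-3, which has the same leading number, Akr1c18 stood at 5.02, lower than in mice 4-1 and 4-2 (log2 -4.92, adjusted p = 0.0394), and this was the single gene that differed between mouse 4-3 and those mice. Over all genes, 273 had an unadjusted p under 0.05 in the F test, where chance gives 523.7. Akr1c18 passed in 24 of the 25 alternative settings in which it was tested (adjusted p 6.90e-05 to 0.0584), all but the one without background correction, and the strict filter left it out of the test. Including Akr1c18, the genes past the threshold numbered 4 without erythroid mouse 2-3, 3 without 2-3-2 and 2 without T-cell mouse 4-2.

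Among the erythroid leukemias, mouse 5-5 differed from the 3 mice of number 2 by 9 genes, all higher in mouse 5-5. Cfb, complement factor B, stood at 9.72 in mouse 5-5 and at a mean of 5.04 in the others (log2 4.67 ± 0.49 SE, limma adjusted p = 0.018). Ubd, a ubiquitin-like modifier induced by cytokines, stood at 8.59 in mouse 5-5 and was detected in none of the others, at least 9.65-fold lower (limma adjusted p = 0.0133). Lpar1, a receptor for lysophosphatidic acid, and Btn1a1, a butyrophilin, were likewise detected in mouse 5-5 alone among the erythroid leukemias, at least 4.26-fold and 3.59-fold above the others. The remaining genes were Il1a, encoding interleukin 1 alpha (3.21 ± 0.43), Parp9, an interferon-induced gene (3.59 ± 0.49), Procr, the receptor of protein C (3.34 ± 0.47), and the unnamed loci LOC225594 (3.52 ± 0.45) and LOC435565 (3.66 ± 0.51). Parp9 and Procr were each detected on 1 array of the number 2 mice, at means of 4.90 and 4.68, so their changes rest on signal close to background. With 1 mouse of number 5 there is no replicate check. The number of genes fell to 0 without T-cell mouse 2, 4-1, 2-2 or 4-2, to 1 without T-cell mouse 5-3, to 2 without T-cell mouse 5 or 5-1 and to 3 without erythroid mouse 2-3-3, and was 0 under median scaling. The number also fell with the first arrays only of mice 5-1 and 5-5. It fell less without the 2 weakest arrays, among them the second array of mouse 5-5. Other settings gave more, such as no filter (91), the mouse as random block (48) and array quality weights (43).

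**Figure D4:**
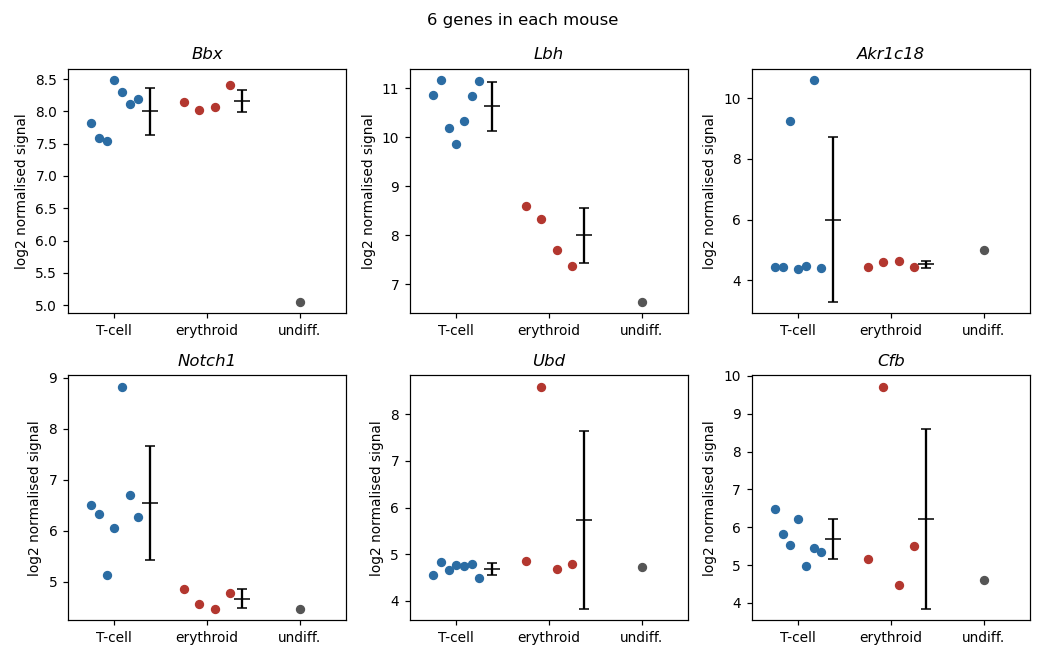
Log2 normalised signal of 6 genes in each mouse by leukemia type, with a point per mouse and a bar for the mean ± SD of the types with more than 1 mouse. Bbx is lowest in the undifferentiated mouse at 5.05, Akr1c18 is high in 2 T-cell mice at 9.27 and 10.61, and Cfb and Ubd are high in 1 erythroid mouse at 9.72 and 8.59.

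The erythroid minus T-cell change was then compared between the leading numbers 5 and 2, which both hold leukemias of both types. No gene passed with limma, 624 had an unadjusted p under 0.05, where chance gives 523.7, and the smallest adjusted p was 0.0577. The count was 2 without erythroid mouse 2-3 and 1 without 2-3-2. On simulated data, 44% of genes with a difference of 4 on the log2 scale were recovered by this test, so smaller differences would mostly not be detectable with these mice.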

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

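The test of a wrong type label for mouse 2-2 was chosen after the result was seen, and so were the fits without the 2 weakest arrays and with the array numbers as a batch.

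The first pattern was the number of genes that differed between erythroid and T-cell leukemias. Of 100 drawn splits of the 11 mice into 7 and 4, 1 gave as many genes, the real one with 1075, and the highest of the others gave 15. The real grouping thus stood out from arbitrary groupings of these mice. The splits treat the mice as independent, and 100 of 330 possible splits were drawn. Since mice 2-3, 2-3-2 and 2-3-3 may be related, the splits cannot tell a difference of type from a relation between mice. Without the 2 weakest erythroid arrays, the median change of the 1075 genes kept 0.858 of its size and all of them kept their sign. With the array number range in the fit it kept 0.980. For these genes, this argues against either as the whole cause. The genes were called with all arrays in the fit and measured again on mostly the same mice, so the kept signs are weak support. Fewer genes passed without the 2 arrays, as given above. These tests bear on the existence of a difference and not on the balance of higher and lower genes, which moved with the scaling.

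The second pattern was mouse 2-2, labelled T-cell, which lay between the types. Its values correlated at r = 0.951 with erythroid mouse 2-3 and at 0.912 at most with another T-cell mouse, its mean of the T-cell receptor list was below that of the lowest other T-cell mouse (7.62), and its erythrocyte membrane mean (8.66) was just under that of the lowest erythroid mouse (8.85). An erythroid leukemia with a wrong label was tested with the mean of the T-cell receptor list in mouse 2-2, 6.79. It exceeded the highest erythroid mouse by 0.782, against an SD of 0.250 over the erythroid mice, but was also below the other T-cell mice. The spleen cells were unsorted, so T cells that are not leukemic may add to this mean. The test can therefore not decide on the label. A mix of cells like those of mice 2 and 2-3 stays open. Of 453 genes that differed by over 2 (log2) between those mice, 96.2% lay in or near the range between them in mouse 2-2. These genes were chosen for their wide gap between mice 2 and 2-3, and the share is not given for any other mouse. The share alone is therefore no evidence of a mix. In mouse 2-2, 1.38% of all genes lay more than 1 above both mouse 2 and mouse 2-3. Among these were Mmp9 and Retnlg of the granulocyte list and Cd163 and Mrc1 of the monocyte list, along with genes of neither list, such as Idi2, Stfa1, Stfa2 and Stfa3. The limits set for this test were not met in either direction. A leukemia that itself held both programs may also be the source and was not tested.

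The third pattern was the wide range of the erythrocyte membrane list among the T-cell leukemias, from 5.53 in mouse 4-2 to 8.66 in mouse 2-2, with adult globin means of 7.05 and 12.76 in these mice. The list mean fell against the T-cell receptor list (r = -0.808, exact permutation p = 0.0218, adjusted 0.0655 over 3 relations; rho = -0.75, p = 0.0663, adjusted 0.199; r = -0.689 without mice 4-2 and 2-2), so a lower share of T-cell leukemia cells where erythroid cells are many may be part of the cause, as a hypothesis that did not pass the adjustment. A lower share that raises all other cell types alike was a separate explanation, under which the B-cell list would rise with the erythroid list. The B-cell list did not rise with it (r = -0.566, exact permutation p = 0.187, adjusted 0.189; rho = -0.5, p = 0.267, adjusted 0.302; r = -0.779 without mice 4-2 and 2-2), which with 7 mice leaves this separate explanation open. The B-cell list does not test a lower share where erythroid cells are many. The number of probes detected stays open too (r = 0.565, exact permutation p = 0.189, adjusted 0.189; rho = 0.464, p = 0.302, adjusted 0.302; r = 0.815 without mice 5 and 4-2). The array number range stays open as well, since mice 4-2 (5.53) and 5-3 (6.17), measured only on arrays 9 to 16, had the lowest means. The ranges held 5 and 3 T-cell mice, fewer than the 6 set for a correlation. No biological explanation other than the share of cells was tested.

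Single mice lay far from the others of their type for some genes and lists. In erythroid mouse 5-5, Dmtn was at 8.22, Cbx6 at 9.89, Ubd at 8.59, Lpar1 at 7.41, Btn1a1 at 7.17 and Procr at 8.02. In erythroid mouse 2-3, H2-DMb2 was at 7.59. Among the T-cell mice, Itga2b at 6.18, Pf4 at 7.85 and Ifit1 at 6.48 stood apart in mouse 2-2, Egr1 at 8.06, Notch1 at 8.83 and Nrarp at 6.29 in mouse 5-1, and Procr at 5.67 in mouse 2. Of the list means, those of the erythrocyte membrane in erythroid mouse 5-5 (9.66), B cells in erythroid mouse 2-3 (6.33) and polycomb repressive complex 1 in erythroid mouse 2-3-2 (5.90) stood apart, as did the Notch pathway in T-cell mouse 5-1 (6.41), megakaryocytes in T-cell mouse 2-2 (6.32) and stromal cells in T-cell mouse 5-3 (6.50). Ubd, Lpar1, Btn1a1 and Procr were named because they were higher in mouse 5-5. Over the 71 genes tested in each type that were not chosen by a comparison of leading numbers, 3 stood apart in erythroid and 6 in T-cell leukemias, where chance gives 3.55 each; over 28 lists it was 3 in each, where chance gives 1.4.

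The array with no type label, which no comparison used, carried signal: 10840 probes were detected on it and its mean of the T-cell receptor list was 8.37.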

How the results depend on the processing

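The fits without the 2 weakest arrays and by array number and the lists with left-out mice were chosen after seeing the data. Of 1092 list medians under an alternative, 54 had the other sign. Of these, 1 belonged to a list past its threshold, polycomb repressive complex 1 between undifferentiated and T-cell leukemias (median -0.11, and 0.07 under median scaling, where camera still called it lower). The median of the monocyte list between undifferentiated and erythroid leukemias went from -0.37 to 0.06 under median scaling, where camera called it lower in the undifferentiated mouse. Within arrays 1 to 8, the erythroid minus T-cell medians of MHC class I (-0.19), CDK inhibitors (-0.12) and cholesterol synthesis (0.06) were 0.29, 0.65 and -0.14. Where a value changed, the cause was not tested, except that the array number ranges hold fewer mice.

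Between erythroid and T-cell leukemias (1075 genes), median scaling gave 431 genes, no filter 577, array quality weights 1993, the fit without the weakest arrays 591, arrays 1 to 8 gave 0 and arrays 9 to 16 gave 179; leaving out single mice gave 460 to 1474. Cyclic loess (809), the authors' value table (1080) and the other settings stayed within 1.5 times, except for the leading number as a block, given below. Of 65 named genes past the threshold, 25 passed under each of the 27 alternatives run for single genes in which they were tested; the fits within each array number range and with the leading number as a block were not among these. For undifferentiated against T-cell (2 genes), no background correction gave 1, offset 50 gave 4, cyclic loess 45, median scaling 1, no filter 17, the strict filter 8, the mouse as random block 5, array quality weights 92, the fit without the weakest arrays 8, leading number 4 only 1, and left-out mice 0 to 63. Against erythroid (1 gene), cyclic loess gave 2, median scaling 0, no filter 10, the strict filter 2, all filtered probes 0, the mouse as random block 0, first arrays 0, trend and robust 0, array quality weights 3, and left-out mice 0 to 9. For the T-cell leading numbers (1 gene), no background correction gave 0, no filter 2, the strict filter 0, the mouse as random block 4, array quality weights 13, the fit without the weakest arrays 3, and left-out mice 1 to 4. For erythroid number 5 against 2 (9 genes), no background correction gave 24, offset 50 gave 19, cyclic loess 4, median scaling 0, no filter 91, the strict filter 0, the mouse as random block 48, first arrays 2, trend and robust 21, array quality weights 43, and left-out mice 0 to 10. For the difference of changes (0 genes with limma, 624 at an unadjusted p under 0.05), no background correction gave 4, offset 50 gave 8, cyclic loess 2, no filter 21, the mouse as random block 21, trend and robust 6, array quality weights 25, the fit without the weakest arrays 1, and left-out mice 0 to 2.

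Lists past camera numbered 0 in all 3 contrasts with an estimated correlation, and 0 with fry in both contrasts of the undifferentiated mouse. Undifferentiated against erythroid (5 lists) gave 11 lists with cyclic loess, 9 with median scaling, 3 with no filter, 8 with all filtered probes and 13 without the weakest arrays. The arrays of mouse 5-5 correlated at 0.901 with cyclic loess. The erythroid Cbx7 signal is an upper limit near background, so the following signal differences measure no change: -0.27, and -0.23 with median scaling, -0.24 with first arrays, -0.27 with trend and robust and -0.33 to -0.22 with left-out mice.

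The leading number as a fixed replicate block gave 109 genes between erythroid and T-cell leukemias, 107 of them among the 1075, and 1 between undifferentiated and T-cell; as a random block it gave 1413. The random block estimated a negative correlation within numbers (-0.115), so its count makes no allowance for mice of a number being alike. The samples share only a number: deviations of 9 same-numbered pairs of different type had a median r of -0.000175 (-0.294 to 0.384), and for 3 of 11 mice the closest mouse of the other type had their own number. This check used pairs of different type. Erythroid mice 2-3, 2-3-2 and 2-3-3 also share a second number and may be related, in which case p-values understate the error; their deviations correlated at -0.787 (2-3 and 2-3-2), 0.314 (2-3 and 2-3-3) and -0.411 (2-3-2 and 2-3-3), where deviations from a shared mean tend below 0. With mice of the same number and type averaged, 1134 genes passed. The slide as a block was not run, since slides are not given in the sources used here. Signal close to background limits the values of probes detected on few arrays, such as Cbx7.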

Other observations

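The values here were chosen after the results were seen. Cholesterol synthesis genes stood at a mean log2 signal of 7.30 in undifferentiated mouse 4-3 and at 6.39 in both other types. Among the T-cell leukemias, granulocyte genes had a mean of 8.85 in mouse 2-2 and 6.96 in mouse 2, and B-cell genes ranged from 5.69 to 7.33. Lbh, lower in mouse 4-3 than in T-cell leukemias, was lower in erythroid leukemias too, at 8.00 ± 0.56 (SD, n = 4) against 10.63 ± 0.50 (SD, n = 7; log2 -2.63, limma adjusted p = 0.0012).

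The array with neither a mouse nor a type in its labels correlated at r = 0.914 with T-cell mouse 5-1 and at 0.739 to 0.869 with the other mice. Its list means were 8.92 for thymocyte, 6.77 for Notch pathway and 6.95 for erythrocyte membrane genes, and Notch1 stood at 9.39. In T-cell mouse 5-1 the thymocyte and Notch means were 8.75 and 6.41.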
